A study of Homo sapiens with 24 samples.

How the data were processed

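RNA from 24 samples (2 fractions, 4 days, 3 replicates) was read on Illumina HT-12 v4 bead arrays after labelling of total RNA as biotinylated cRNA. The probe intensity values are deposited without normalisation and, per the submitters' notes, were exported from GenomeStudio 2011.1 by the authors. Beside each intensity the deposited table holds a fraction headed as a detection p, which the values show to be 1 minus p in steps of 770 negative controls, so the planned filter was applied to 1 minus the stored value. The deposited series matrix holds log2 values, which match the log2 intensities minus a constant per array (its 75th percentile) and a baseline per probe, so only differences between arrays were used from it. The files carry no probe names in common, so all 47323 probes were joined one to one by their values. No genome build is named, and no coordinates are given.

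Of these probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 were unnamed. TNNT2 and SOX17, chosen in advance, are not analysed here. Intensities were corrected with limma 3.58.1 (nec with detection p, offset 16), quantile normalised and put on the log2 scale in R 4.3.3. Probes were kept when detected (p under 0.05) in all 3 replicates of at least 1 group, which left 21328 probes, 16596 of them with 1 symbol. Each gene was represented by its probe of highest mean, which gave 12573 genes after 5 sex-linked ones were left out. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scikit-learn 1.9.0, and figures drawn with matplotlib 3.10.9.

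Median intensity per array was 95.2 to 127.8, and 40.3% to 45.8% of probes were detected. Replicates of a group correlated with r from 0.9405 to 0.9884 across genes, which are not independent replicates. A linear model with 8 group means over all 24 arrays (16 residual degrees of freedom) was fitted in limma with empirical Bayes moderation along the intensity trend. The comparisons were the fractions on each day, day 14 against day 5 in each fraction, successive days in the positive fraction, the difference of the day 14 versus day 5 changes and an F-test over the 3 interaction terms. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and calls at adjusted p under 0.05. For 30 lists of 622 members, 580 of them annotated, limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. These choices were made before the data were examined.

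Genes were named by a rule set in advance. It takes the 6 largest rises and the 6 largest falls among called genes whose groups do not overlap, 2 to 4 members of each list described (those called with the largest change, or those of smallest p), and 17 fixed genes. Locus-number symbols are left out.

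The steps were tested on simulated data with these arrays' means and pooled spreads but no replicate pairing. In the positive fraction 200 genes were changed at day 14. That day 20.9%, 50.7% and 93.9% were recovered at 1.5-, 2- and 4-fold, with 5 unchanged genes called. For the difference of changes shares were 2.99%, 23.9% and 80.3%, with 2 unchanged called. At day 5, with none changed, 0 were called.

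Alternatives were other background corrections, cyclic loess, scaling to the 75th percentile, the authors' values (with the moderation trend taken over probe brightness), no or a stricter detection filter, all probes, a 2-fold or an adjusted p of 0.01 threshold, array weights, the replicate number as a block, only the arrays compared, and leaving out each array. Whether replicate numbers pair the samples was checked on residuals. Arrays of the same number correlated between fractions within a day (0.25 to 0.655), and those of the positive fraction did so between days 7 and 10 and days 10 and 14 (0.302 to 0.656), each best with its own number. Day 5 did not pair with day 14 in either fraction or with day 7 in the positive one (-0.238 to 0.136), and other pairs of days were not run. The successive-day comparisons rest on a model without a block. A block within each day and the exclusion of 6 arrays were therefore added after the data were seen.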

Results

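Human embryonic stem cells were differentiated towards the heart, and on day 3 the culture was sorted on an mCherry reporter of MESP1, a transcription factor of the early mesoderm from which the heart forms. The mCherry-positive and the mCherry-negative fraction were each replated as aggregates with Xav939, an inhibitor of Wnt signalling, and RNA was taken on days 5, 7, 10 and 14. Each of the 8 combinations of fraction and day had 3 replicates, read on 24 Illumina bead arrays, and the stated aim was to find regulators and cell surface markers of the cardiac lineage. The labels do not say that replicates came from separate cultures, so every p-value measures only the spread between these samples. A gene whose call changed in an alternative is said to have passed or failed there, with its adjusted p in brackets, and the range after it spans the adjusted p over all alternatives run for that gene or list. Scaling is to the 75th percentile, normexp and no correction refer to the background, loess is cyclic, arrays 3 are the 6 numbered 3 of days 7, 10 and 14, and a reduced model holds only the arrays compared. The replicate block has the replicate number as a block in the model, and the daily block the replicate number within each day.

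Levels are normalised log2 intensities with their SD, n is 3 arrays per group throughout, and a value with ± in brackets after a gene is its log2 fold change with its standard error in limma's model of all 24 arrays. Where a gene was detected on no array of 1 group, the difference is written as at least N-fold, a lower bound against the dimmest signal still detected. Genes named for the largest differences had groups whose 3 arrays did not overlap, which chance alone gives in 10% of cases. Lists of genes were fixed before the data were examined. Beside the number of members called over all genes, list-alone numbers are those called when adjusted over the list alone. Dim marks a gene detected on 1 or 2 of the 3 arrays of a group, whose size rests partly on background. MYH6 reached 14.02 on days 7 to 14, near the top of the scale (14.11, the highest value of any gene), so its rises from day 5 are lower bounds and its differences among later groups (adjusted p from 0.223 to 1) are not read. A list's test is limma's camera with a preset correlation between genes. Lists share members, such as SOX2 in the pluripotency and neuroectoderm lists, CDH1 and EPCAM in the endoderm and surface ectoderm lists and PDGFRA in the matrix and surface marker lists.

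**Figure D1:**
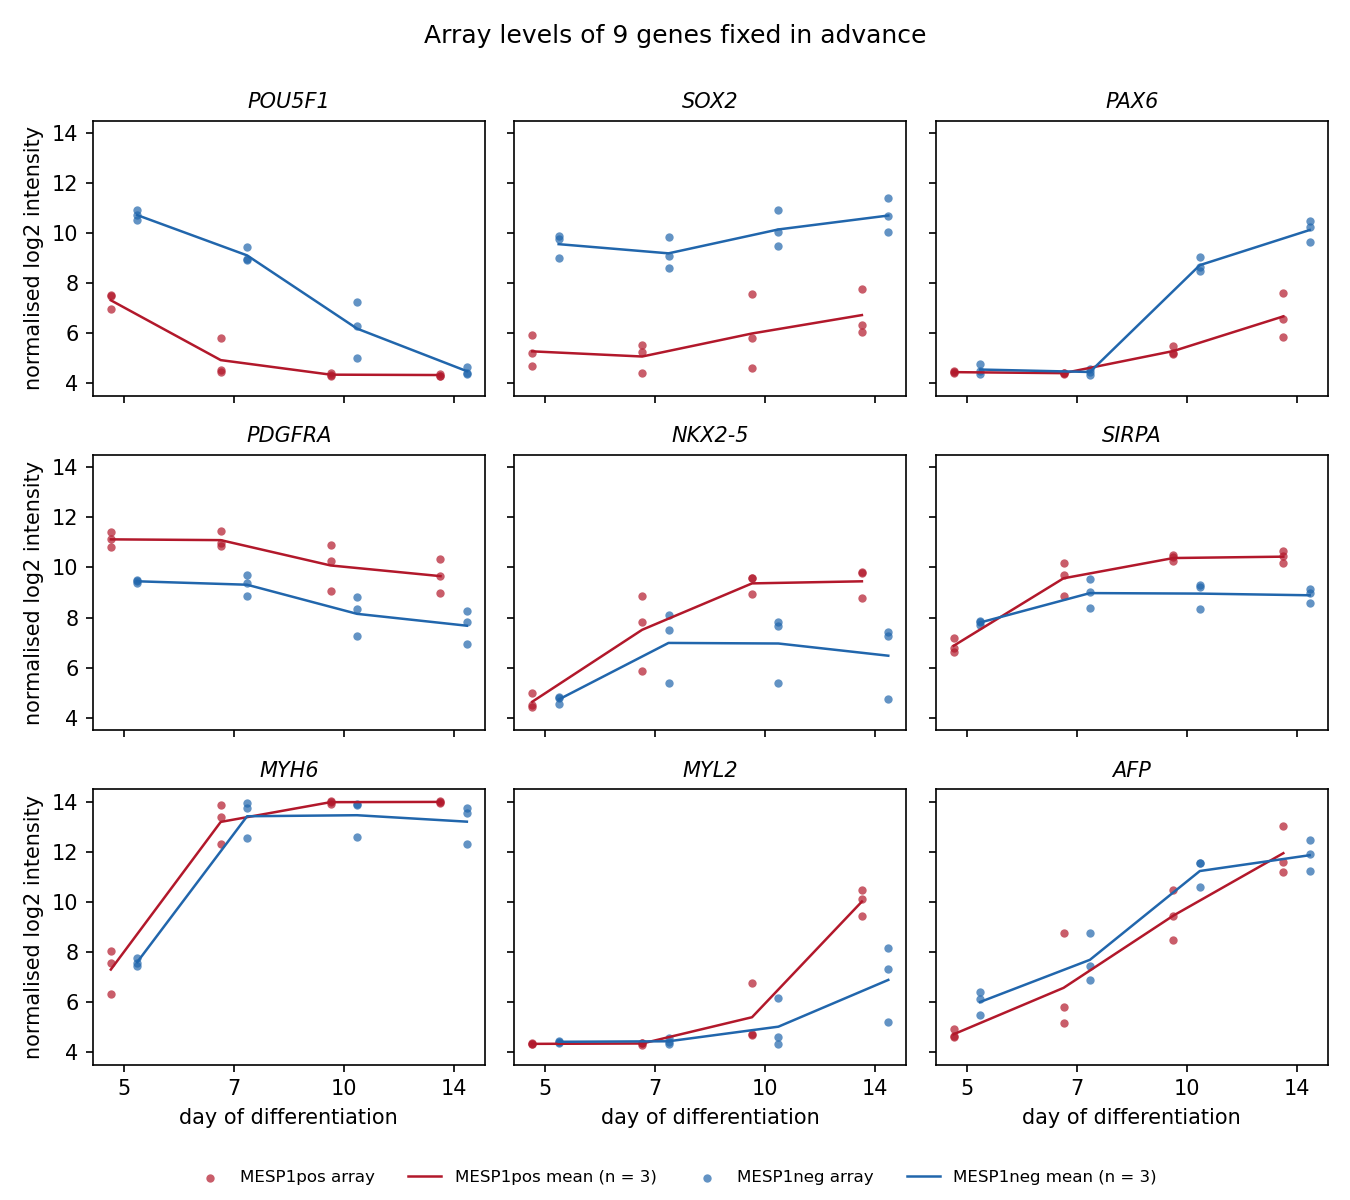
Normalised log2 intensity of 9 genes (vertical axes) on the 4 days of differentiation (horizontal axes), with a point for each array and lines joining the means of 3 arrays of the MESP1-positive and the MESP1-negative fraction. POU5F1 and SOX2 lay higher in the negative fraction on day 5, and PAX6 lay higher there on days 10 and 14.

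MESP1 RNA itself was near background in all groups, with group means from 4.63 to 5.44 on the log2 scale. It was detected on all 3 arrays of the positive fraction at day 5 and on 1 of the 3 of the negative fraction. The fractions did not differ in MESP1 RNA at day 5 (log2 fold change 0.45 ± 0.34, limma adjusted p = 0.479) or on any later day (adjusted p from 0.386 to 0.794). The sort preceded the first arrays by 2 days, so these values neither check nor contradict the fraction labels.

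In both fractions the arrays numbered 3 of days 7, 10 and 14 differed from the mean of the other replicates in the gene lists given here. Over these 6 groups, array 3 minus the mean of the other replicates had a median between 0.46 and 1.59 log2 units for the sarcomere genes, between -1.49 and -0.70 for the fibroblast and matrix genes and between -1.86 and -0.27 for the epicardium genes. The mean difference was -2.77 for RNA28SN5 and 2.33 for CKM.

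On day 5, 2 days after the sort, the MESP1-negative fraction held far more RNA of pluripotency genes. POU5F1, the core factor of the pluripotent state, stood at 10.72 ± 0.20 in the negative and 7.32 ± 0.32 in the positive fraction, a 10.6-fold difference (limma adjusted p = 2.59e-06). SOX2 (-4.28 ± 0.60, dim), shared by stem and neural cells, was 19.4-fold lower in the positive fraction, and PRDM14 (at least 13.8-fold), a repressor that guards pluripotency, was lower too. The positive fraction held more RNA of PDGFRA (1.67 ± 0.43), a receptor of cardiac mesoderm, of GATA6 (1.74 ± 0.23, dim) and IRX5 (1.81 ± 0.47), transcription factors of the forming heart, and of CD82 (2.23 ± 0.25), a tetraspanin of the cell surface. CDH1 (-3.76 ± 0.74), which encodes E-cadherin of epithelial junctions, was lower.

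Pluripotency genes were lower for 11 of 14 (12 list-alone), with SOX2 and PRDM14 (camera adjusted p = 1.37e-16, adjusted p = 0.00182 with estimated correlation). Neuroectoderm genes were lower for 7 of 18 (7 list-alone), with SOX2 and ZIC2 (-3.28 ± 0.40) (camera adjusted p = 8.17e-05, adjusted p = 0.00523 with estimated correlation). In the positive fraction surface ectoderm and epithelium genes were lower for 5 of 13 (6 list-alone), with CDH1 and TFAP2C (-3.39 ± 0.38, dim) (camera adjusted p = 0.00113, adjusted p = 0.52 with estimated correlation). Cardiac transcription factors were higher for 5 of 20 (7 list-alone), with IRX5 and GATA6 (camera adjusted p = 0.00113, adjusted p = 0.444 with estimated correlation). Heart progenitor surface markers were higher for 5 of 17 and lower for 3 (5 and 3 list-alone), with CD82 and KIT (-1.88 ± 0.30) (camera adjusted p = 0.671). Of 24 sarcomere genes 1 was higher, MYL7 (1.79 ± 0.57), an atrial myosin light chain, and 0 list-alone (camera adjusted p = 0.671). Other lists that were lower were definitive endoderm and gut and glycolysis (camera adjusted p from 0.0352 to 0.044), with adjusted p from 0.236 to 0.939 with estimated correlation.

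The largest excesses in the positive fraction were in PANX2 (3.86 ± 0.27), a membrane channel protein, SMOC1 (3.36 ± 0.42), a matrix protein, CALB2 (3.32 ± 0.36), the calcium-binding calretinin, the collagen gene COL22A1 (3.27 ± 0.46), PTGDS (3.11 ± 0.28, dim), a prostaglandin synthase, and ATP6V1B1 (2.89 ± 0.40), a proton pump subunit. The largest deficits besides SOX2 and PRDM14 were in CFAP95 (-4.53 ± 0.29), a cilium-associated protein, the neural factor SOX21 (-4.14 ± 0.45, dim), CAMKV (-4.13 ± 0.32), a kinase-like protein, and the cadherin CDH6 (-3.95 ± 0.19, dim). SIRPA (-0.93 ± 0.30), a surface marker of heart muscle cells, was lower at this stage (adjusted p = 0.0488). AFP (-1.29 ± 0.71, dim), ISL1 (0.39 ± 0.42), MYH6 (-0.30 ± 0.46), PECAM1 (0.21 ± 0.40, dim), KDR (0.21 ± 0.42), MKI67 (0.06 ± 0.24) and NKX2-5 (not detected in the negative fraction) did not pass (adjusted p from 0.291 to 0.975), and MYL2, VCAM1 and PAX6 were detected in neither group.

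In all, 651 genes were higher and 884 lower at limma's adjusted p under 0.05. The count of higher genes was 430 and 326 without positive-fraction replicates 1 and 3 and 382 and 369 without negative-fraction replicates 2 and 3. Higher and lower genes numbered 1409 and 1436 with array weights, and higher genes alone 1261 with the daily block and 1036 with a reduced model. MYL7 failed without positive replicates 1 (0.0699), 2 (0.15) and 3 (0.0933) and negative replicates 1 (0.108), 2 (0.0966) and 3 (0.114) and with loess (0.0628), scaling (0.0559), authors' values (0.0554) and no filter (0.0579), range 0.000151 to 0.15. IRX5 failed without positive replicates 2 (0.0511) and 3 (0.0544) and negative replicate 3 (0.0677), range 0.000412 to 0.0677. SIRPA failed without positive replicates 2 (0.158) and 3 (0.144) and negative replicates 1 (0.0952), 2 (0.127) and 3 (0.127) and with normexp (0.108), no correction (0.154), authors' values (0.0906) and no filter (0.0648), range 0.0041 to 0.158. PDGFRA failed without positive replicate 3 (0.0658), range 4.41e-05 to 0.0658. AFP (0.00581, range 0.00581 to 0.699) passed with a reduced model. Among lists, glycolysis had adjusted p = 0.0791 with authors' values (range 0.0103 to 0.939) and definitive endoderm and gut had 0.0609 with the daily block (range 0.0119 to 0.236).

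On day 7 pluripotency, epithelial and ectoderm lists were higher in the negative fraction. Cell identity was not tested. POU5F1 stood at 9.11 ± 0.31 in the negative and 4.93 ± 0.75 in the positive fraction, 18.1-fold apart (adjusted p = 4.76e-07), and SOX2 (-4.12 ± 0.60, dim) was lower too. TFAP2A (-4.40 ± 0.51) and TFAP2C (-4.36 ± 0.38, dim), transcription factors of surface ectoderm, DLX5 (-4.58 ± 0.40, dim), a homeobox factor, and SCNN1A (-4.50 ± 0.40, dim), a subunit of the epithelial sodium channel, were lower in the positive fraction. That fraction held more NR2F1 (3.29 ± 0.36), a nuclear receptor of atrial identity, and more PDGFRA (1.78 ± 0.43). MYH6, the alpha myosin heavy chain, stood at 13.19 ± 0.79 and 13.42 ± 0.76, near the top of the scale in both fractions.

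Surface ectoderm and epithelium genes were lower for 10 of 13 (10 list-alone), with TFAP2C and EPCAM (-3.37 ± 0.26), an epithelial adhesion molecule (camera adjusted p = 4.13e-12, adjusted p = 0.0258 with estimated correlation). Pluripotency genes were lower for 9 of 14 (11 list-alone), with POU5F1 and SOX2 (camera adjusted p = 5.01e-11, adjusted p = 0.0157 with estimated correlation). Neuroectoderm genes were lower for 7 of 18 and higher for 1 (9 and 1 list-alone), with DLX5 and ZIC2 (-4.26 ± 0.40, dim) (camera adjusted p = 0.00114, adjusted p = 0.0254 with estimated correlation). Cell cycle genes were lower for 10 of 27 (12 list-alone), with BUB1 (-1.17 ± 0.24), a spindle checkpoint kinase, and MCM5 (-1.10 ± 0.15), a subunit of the DNA replication helicase (camera adjusted p = 2e-07, adjusted p = 0.569 with estimated correlation). Cardiac transcription factors were higher for 5 of 20 and lower for 1 (8 and 2 list-alone), with HAND2 (1.68 ± 0.47) and ZFPM2 (1.54 ± 0.37) (camera adjusted p = 0.018, adjusted p = 0.619 with estimated correlation). Heart progenitor surface markers were higher for 4 of 17 and lower for 1 (5 and 2 list-alone), with KIT (-2.52 ± 0.30) and PDGFRA (camera adjusted p = 0.241). Of 24 sarcomere genes 1 was higher, TNNI1 (at least 1.11-fold), and 0 list-alone. The sarcomere list's median log2 fold change was -0.10 and its mean -0.03, whereas the test pointed upwards without passing (camera adjusted p = 0.747). The fibroblast and matrix list was the only other one that was higher (camera adjusted p = 0.0155, adjusted p = 0.874 with estimated correlation). The definitive endoderm and gut list was the only other one that was lower (camera adjusted p = 0.00874, adjusted p = 0.08 with estimated correlation).

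The largest other excesses were in COL11A1 (2.86 ± 0.37), a fibrillar collagen, LAMP5 (2.74 ± 0.34), a lysosome-associated membrane protein, SFRP5 (2.55 ± 0.67), a secreted Wnt antagonist, TECRL (2.39 ± 0.49), an endoplasmic reticulum protein of heart muscle, and LRRC3B (2.32 ± 0.45, dim). KCNK12 (-4.73 ± 0.45), a potassium channel, had the largest deficit, 26.6-fold (adjusted p = 5.41e-07). ISL1 (-1.08 ± 0.42), SIRPA (0.59 ± 0.30), VCAM1 (1.13 ± 0.68, dim), AFP (-1.12 ± 0.71), PECAM1 (0.58 ± 0.40, dim), KDR (0.56 ± 0.42), MKI67 (0.25 ± 0.24) and NKX2-5 (0.52 ± 0.78) did not pass (adjusted p from 0.111 to 0.75), and MYL2 and PAX6 were detected in neither group.

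At limma's adjusted p under 0.05, 514 genes were higher and 849 lower. The count of higher genes was 294 without positive-fraction replicate 1 and 234 without negative-fraction replicate 1, which also brought the lower genes to 530. Higher and lower genes numbered 1194 and 1378 with the daily block, 1282 and 1484 with array weights, 158 and 390 with a reduced model and 224 and 533 with authors' values, and higher genes alone 800 with the replicate block. PDGFRA failed without positive replicate 1 (0.0516), range 7.1e-05 to 0.0516. HAND2 failed without positive replicates 1 (0.0963) and 3 (0.0738) and negative replicate 1 (0.142) and with arrays 3 left out (0.127), range 0.00546 to 0.142. TNNI1 failed without positive replicates 1 (0.12) and 3 (0.115) and negative replicates 1 (0.124) and 3 (0.112) and with loess (0.116), scaling (0.0619), authors' values (0.136), daily block (0.0526), arrays 3 left out (0.162) and a reduced model (0.157), range 0.00316 to 0.162. SFRP5 failed without positive replicate 1 (0.0639) and negative replicates 1 (0.0644) and 3 (0.0615), range 0.00115 to 0.0644. SIRPA passed without positive replicate 2 (0.0389) and with array weights (0.0304), range 0.0304 to 0.679. AFP passed without positive replicate 2 (0.0172) and with array weights (0.0161), range 0.0161 to 0.925. ISL1 passed with daily block (0.026) and arrays 3 left out (0.0451), range 0.026 to 0.526. VCAM1 passed with daily block (0.0382) and array weights (0.046), range 0.0382 to 0.809. BUB1 (0.0513, range 3.77e-05 to 0.0513) failed with arrays 3 left out. ZFPM2 (0.074, range 0.000402 to 0.074) failed with a reduced model. Among lists, neuroectoderm had adjusted p = 0.0955 with authors' values (range 0.00108 to 0.0955) and cardiac transcription factors had 0.055 with arrays 3 left out (range 0.0163 to 0.619).

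On day 10 NKX2-5 (2.40 ± 0.78), a founding transcription factor of the heart, stood at 9.37 ± 0.37 in the positive and 6.97 ± 1.36 in the negative fraction, 5.28-fold apart (adjusted p = 0.0312). SIRPA (1.42 ± 0.30) was 2.68-fold and PDGFRA (1.93 ± 0.43) 3.81-fold higher in the positive fraction. PAX6 (-3.43 ± 0.30), a factor of forebrain and eye, was 10.8-fold lower, and RAX (-4.58 ± 0.28, dim), a factor of the eye field, 23.9-fold lower. POU5F1 (at least 2.47-fold) was lower in the positive fraction, where it was not detected.

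Cardiac transcription factors were higher for 13 of 20 (15 list-alone), with NKX2-5 and GATA5 (2.32 ± 0.32) (camera adjusted p = 9.44e-08, adjusted p = 0.054 with estimated correlation). Sarcomere genes were higher for 9 of 24 (18 list-alone), with TTN (2.16 ± 0.58), which encodes titin, and LDB3 (2.08 ± 0.68), a protein of the Z-disc (camera adjusted p = 8.95e-07, adjusted p = 0.347 with estimated correlation). Calcium handling and ion channel genes were higher for 10 of 19 and lower for 1 (10 and 1 list-alone), with HRC (2.15 ± 0.72), a calcium-binding protein of the sarcoplasmic reticulum, and GJA1 (-2.06 ± 0.27), a gap junction gene (camera adjusted p = 0.000947, adjusted p = 0.197 with estimated correlation). Cell cycle genes were lower for 26 of 27 (26 list-alone), with AURKB (-1.84 ± 0.16), a mitotic kinase, and CCNB2 (-1.83 ± 0.17), a mitotic cyclin (camera adjusted p = 6.94e-22, adjusted p = 0.054 with estimated correlation). Neuroectoderm genes were lower for 13 of 18 and higher for 1 (15 and 2 list-alone), with ZIC2 (-4.47 ± 0.40) and SOX2 (-4.15 ± 0.60, dim) (camera adjusted p = 1.92e-11, adjusted p = 8.12e-05 with estimated correlation). Heart progenitor surface markers were higher for 4 of 17 and lower for 1 (4 and 1 list-alone), with PDGFRA and SIRPA (camera adjusted p = 0.171). Further lists that were higher were atrial or ventricular genes, smooth muscle, endothelium, fibroblast and matrix, oxidative phosphorylation and fatty acid oxidation (camera adjusted p from 1.78e-06 to 0.0267), with adjusted p from 0.0863 to 0.575 with estimated correlation. Further lists that were lower were pluripotency, liver and yolk sac endoderm, neural crest and surface ectoderm (camera adjusted p from 1.19e-06 to 0.00173), with adjusted p from 0.054 to 0.482 with estimated correlation.

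Among single genes the largest excesses were in COL8A1 (3.73 ± 0.50, dim), a short-chain collagen, the pepsinogen genes PGA5 (3.48 ± 0.61) and PGA3 (3.38 ± 0.57, dim), near-identical copies that probes can hardly tell apart, WNT2 (3.09 ± 0.48), a Wnt ligand, RASD1 (2.90 ± 0.51), a small GTPase, and GATM (2.90 ± 0.60), an enzyme of creatine synthesis. The largest deficits besides RAX, ZIC2 and SOX2 were in SOX21 (-4.54 ± 0.45, dim), CAMKV (at least 13.6-fold) and ALPL (-3.88 ± 0.30), an alkaline phosphatase. MKI67 (-0.96 ± 0.24, dim), a marker of cycling cells, was lower (adjusted p = 0.00671) and KDR (1.26 ± 0.42, dim), a receptor of vascular progenitors, higher (adjusted p = 0.0344). AFP (-1.78 ± 0.71), VCAM1 (1.65 ± 0.68), PECAM1 (0.89 ± 0.40, dim), ISL1 (0.75 ± 0.42) and MYL2 (0.38 ± 0.58, dim) did not pass (adjusted p from 0.0775 to 0.701).

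At limma's adjusted p under 0.05, 1308 genes were higher and 1466 lower. Without negative-fraction replicate 1 the higher genes numbered 778. Higher and lower genes numbered 802 and 907 with a reduced model and 820 and 954 with authors' values, and higher genes alone 2212 with the daily block. NKX2-5 failed without positive replicates 2 (0.0889) and 3 (0.0777) and negative replicate 1 (0.2), range 0.00379 to 0.2. LDB3 failed without positive replicates 2 (0.0699) and 3 (0.103) and negative replicate 1 (0.222), range 0.00225 to 0.222. HRC failed without positive replicates 2 (0.091) and 3 (0.0906) and negative replicate 1 (0.209), range 0.00451 to 0.209. KDR failed without positive replicate 2 (0.145) and negative replicates 1 (0.0764) and 3 (0.185) and with scaling (0.0537), authors' values (0.0998), no filter (0.0546), arrays 3 left out (0.137) and a reduced model (0.0567), range 0.00965 to 0.185. AFP passed without positive replicate 2 (0.0496) and with normexp (0.0404), no correction (0.0311), authors' values (0.0143), replicate block (0.0235), daily block (0.0202) and a reduced model (0.0429), range 0.0143 to 0.267. TTN failed without negative replicate 1 (0.0787), range 0.000945 to 0.0787. VCAM1 passed without negative replicate 3 (0.0435) and with no correction (0.0425), replicate block (0.0126), daily block (0.0026), array weights (0.0116) and arrays 3 left out (0.0274), range 0.0026 to 0.388. PECAM1 passed with daily block (0.0441) and array weights (0.0376), range 0.0376 to 0.536.

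On day 14 MYL2 (3.13 ± 0.58), the ventricular myosin light chain, stood at 10.01 ± 0.52 in the positive and 6.88 ± 1.52 in the negative fraction, 8.75-fold apart (adjusted p = 0.000382). RYR2 (3.19 ± 0.56), the calcium release channel of heart muscle, was 9.15-fold and NKX2-5 (2.97 ± 0.78, dim) 7.84-fold higher. ITLN1 (5.65 ± 0.73, dim), a lectin of mesothelium, was 50.2-fold higher, with an SD of 2.24 in the positive fraction. HES5 (-5.05 ± 0.38), a Notch target of neural progenitors, was 33.1-fold lower and FABP7 (-4.47 ± 0.30), a fatty acid carrier of radial glia, 22.2-fold lower.

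Sarcomere genes were higher for 21 of 24 (22 list-alone), with MYL2 and TNNC1 (2.85 ± 0.81) (camera adjusted p = 2.79e-09, adjusted p = 0.233 with estimated correlation). Cardiac transcription factors were higher for 17 of 20 (18 list-alone), with NKX2-5 and TBX18 (2.85 ± 0.44, dim) (camera adjusted p = 2.58e-09, adjusted p = 0.056 with estimated correlation). Calcium handling and ion channel genes were higher for 11 of 19 and lower for 1 (12 and 1 list-alone), with RYR2 and KCNA5 (2.48 ± 0.59), an atrial potassium channel (camera adjusted p = 0.000125, adjusted p = 0.151 with estimated correlation). Epicardium genes were higher for 7 of 14 (11 list-alone), with ITLN1 and TBX18 (camera adjusted p = 8.4e-05, adjusted p = 0.214 with estimated correlation). Their median on positive-fraction array 3 lay -1.86 from the other replicates. Oxidative phosphorylation genes were higher for 17 of 21 and lower for 1 (19 and 1 list-alone), with PPARGC1A (2.33 ± 0.60), a coactivator of mitochondrial genes, and COX6A2 (1.62 ± 0.53, dim) (camera adjusted p = 7.33e-07, adjusted p = 0.214 with estimated correlation). Cell cycle genes were lower for 26 of 27 (27 list-alone), with AURKB (-1.89 ± 0.16) and CCNB2 (-1.85 ± 0.17) (camera adjusted p = 5.28e-19, adjusted p = 0.0964 with estimated correlation). Neuroectoderm genes were lower for 13 of 18 and higher for 1 (13 and 1 list-alone), with HES5 and FABP7 (camera adjusted p = 2.61e-11, adjusted p = 8.74e-05 with estimated correlation). Heart progenitor surface markers were higher for 6 of 17 and lower for 2 (8 and 3 list-alone), with PDGFRA (1.98 ± 0.43) and KIT (-1.73 ± 0.30) (camera adjusted p = 0.208). Further lists that were higher were atrial or ventricular genes, smooth muscle, endothelium, fibroblast and matrix and fatty acid oxidation (camera adjusted p from 8.4e-05 to 0.0123), with adjusted p from 0.146 to 0.602 with estimated correlation. The pluripotency list was the only other one that was lower (camera adjusted p = 0.000125, adjusted p = 0.146 with estimated correlation).

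Other large excesses were in SBSPON (3.49 ± 0.74), a matrix-associated protein, SYNPO2L (3.29 ± 0.66), a protein of the Z-disc, WNT2 (3.27 ± 0.48, dim) and FITM1 (3.21 ± 0.62), a lipid droplet protein of muscle. Other large deficits were in SOX21 (-4.75 ± 0.45, dim), SP8 (-4.20 ± 0.27), a transcription factor of the forebrain, MIAT (-4.07 ± 0.31), a long noncoding RNA, and TTYH1 (-4.02 ± 0.26), a membrane protein of neural cells. SIRPA (1.54 ± 0.30) was 2.91-fold (adjusted p = 0.000626), ISL1 (1.28 ± 0.42), a factor of cardiac progenitors, 2.43-fold (adjusted p = 0.0261) and KDR (1.36 ± 0.42, dim) 2.57-fold higher (adjusted p = 0.0176), while PAX6 (-3.45 ± 0.30), SOX2 (-3.98 ± 0.60) and MKI67 (-1.13 ± 0.24, dim) were lower (adjusted p = 6.25e-08, 4.9e-05 and 0.00132). VCAM1 (1.77 ± 0.68), PECAM1 (0.80 ± 0.40, dim) and AFP (0.08 ± 0.71) did not pass (adjusted p from 0.056 to 0.953), and POU5F1 was detected in neither group.

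At day 14, 1817 genes were higher and 1769 lower at limma's adjusted p under 0.05. Over the 4 days 96 genes were higher and 171 lower in the positive fraction on every day, and 5287 were called on at least 1 day. Days 10 and 14 shared 996 higher genes (189 if independent) and 1031 lower genes (206). Higher genes numbered 1156 with authors' values. ISL1 failed without positive replicates 1 (0.1) and 2 (0.059) and negative replicates 1 (0.0662) and 3 (0.136) and with authors' values (0.0639) and arrays 3 left out (0.0842), range 0.00491 to 0.136. VCAM1 passed without positive replicate 1 (0.0286) and negative replicate 3 (0.0409) and with normexp (0.0236), no correction (0.016), authors' values (0.0381), replicate block (0.00624), daily block (0.00123), array weights (0.0167) and arrays 3 left out (0.0295), range 0.00123 to 0.24. COX6A2 failed without positive replicates 2 (0.0667) and 3 (0.108) and negative replicate 1 (0.136) and with authors' values (0.05), range 4.95e-06 to 0.136. KDR failed without positive replicate 2 (0.0749) and negative replicate 3 (0.0645) and with authors' values (0.0626) and arrays 3 left out (0.0689), range 0.00486 to 0.0749. NKX2-5 failed without negative replicate 1 (0.0605), range 0.00063 to 0.0605. TNNC1 failed without negative replicate 1 (0.0844), range 0.000258 to 0.0844. PECAM1 (0.05, range 0.05 to 0.526) passed with array weights.

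**Figure D2:**
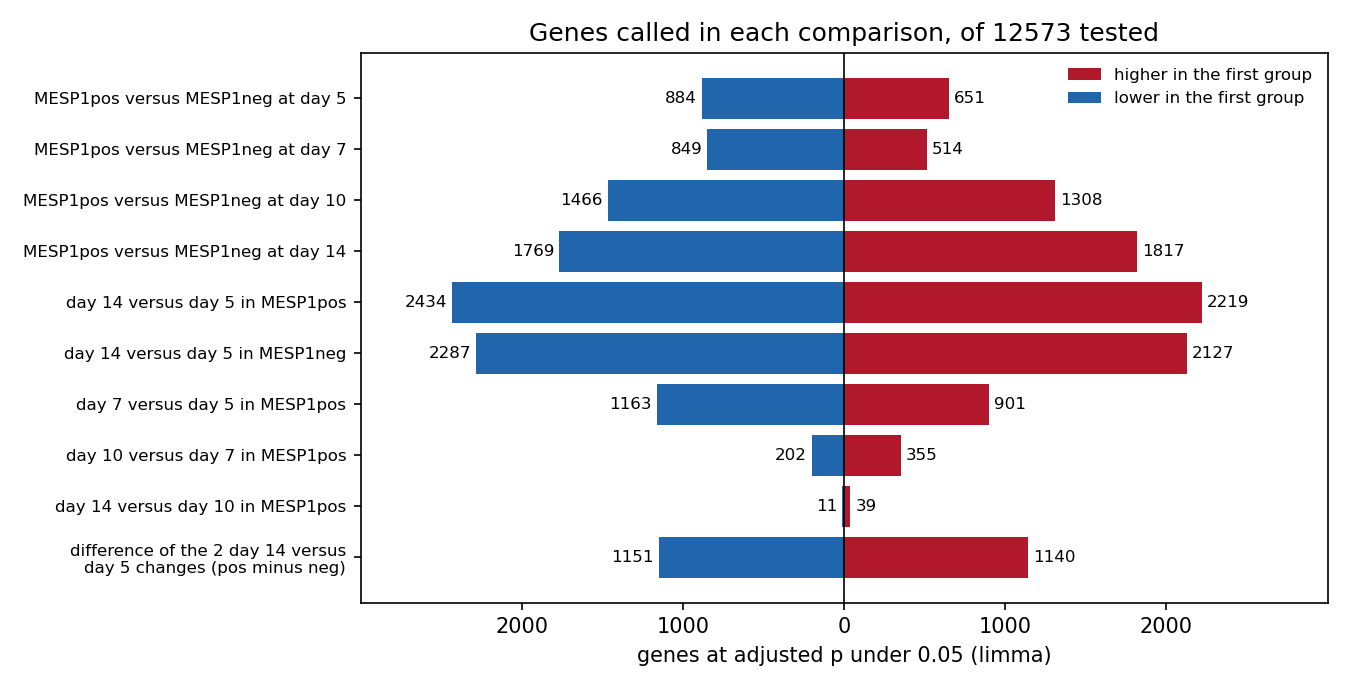
Number of genes at limma's adjusted p under 0.05 in each comparison (horizontal axis, of 12573 genes tested), with bars to the right for genes higher and to the left for genes lower in the group named first. The fractions differed in 651 and 884 genes at day 5 and in 1817 and 1769 at day 14.

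An F-test for a change of the fraction difference over the days called 1930 genes (15.4%). The day 14 versus day 5 change in the positive minus that in the negative fraction was called upwards for 1140 genes and downwards for 1151. Upward and downward genes numbered 1988 and 1936 with the daily block and 1763 and 1758 with array weights. The F-test called 3660 with the daily block and 3618 with array weights. MYL2 (3.21 ± 0.82) gained more in the positive fraction (adjusted p = 0.00924), and so did SIRPA (2.47 ± 0.43) (adjusted p = 0.000433). PAX6 (-3.35 ± 0.42) gained less (adjusted p = 1.46e-05), and POU5F1 (3.25 ± 0.55), already low in the positive fraction on day 5, lost less (adjusted p = 0.000335).

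Sarcomere genes gained more for 9 of 24 (13 list-alone), with TNNI3 (3.42 ± 0.91), cardiac troponin I, and MYL2 (camera adjusted p = 5.34e-06, adjusted p = 0.351 with estimated correlation). Cardiac transcription factors gained more for 4 of 20 (6 list-alone), with TBX18 (2.95 ± 0.62) and HEY2 (2.54 ± 0.50) (camera adjusted p = 0.00481, adjusted p = 0.351 with estimated correlation). Epicardium genes gained more for 3 of 14 (3 list-alone), with ITLN1 (5.67 ± 1.03) and TBX18 (camera adjusted p = 0.00508, adjusted p = 0.351 with estimated correlation). For cell cycle genes the change was below that of the negative fraction for 20 of 27 (22 list-alone), with CENPF (-1.90 ± 0.30) and TPX2 (-1.73 ± 0.50) (camera adjusted p = 7.11e-14, adjusted p = 0.35 with estimated correlation). Neuroectoderm genes gained less for 7 of 18 and gained more for 1 (8 and 1 list-alone), with FABP7 (-4.55 ± 0.43) and SIX3 (-3.62 ± 0.47) (camera adjusted p = 0.000374, adjusted p = 0.0289 with estimated correlation). Other lists shifted upwards were pluripotency, calcium handling and ion channels, surface ectoderm, oxidative phosphorylation, fatty acid oxidation, glycolysis, Wnt pathway and BMP and TGF-beta pathway (camera adjusted p from 3.32e-07 to 0.0469), with adjusted p from 0.351 to 0.467 with estimated correlation.

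The other largest upward differences were in ADGRG2 (5.57 ± 0.64), an adhesion receptor, NMRK2 (5.27 ± 0.79), a kinase of muscle that feeds NAD synthesis, ADM (4.50 ± 0.56), which encodes adrenomedullin, PLAAT3 (4.49 ± 0.45), a phospholipase, and SMPDL3B (4.48 ± 0.36), a phosphodiesterase. The downward ones were in ATP6V1B1 (-5.64 ± 0.57), ZBTB16 (-4.51 ± 0.58), a zinc finger repressor, GRM3 (-4.13 ± 0.60), a glutamate receptor, CCKBR (-4.06 ± 0.60), a peptide receptor, and DIPK1C (-3.98 ± 0.54). MKI67 (-1.19 ± 0.34) was called downwards (adjusted p = 0.019). NKX2-5 (3.06 ± 1.10), KDR (1.16 ± 0.59), VCAM1 (1.80 ± 0.96), ISL1 (0.89 ± 0.59), AFP (1.37 ± 1.00), PECAM1 (0.60 ± 0.57), PDGFRA (0.31 ± 0.61), SOX2 (0.31 ± 0.85) and MESP1 (-0.03 ± 0.48) did not pass (adjusted p from 0.0587 to 0.975). ITLN1, MYL2, VCAM1 and PAX6 were detected on no day 5 array, POU5F1 on no day 14 array, and NKX2-5, DIPK1C, SIX3 and TNNI3 on no day 5 array of 1 fraction, so their sizes rest on signals at background. MKI67 failed without positive day 14 replicate 2 (0.0512) and negative day 14 replicate 1 (0.0602) and with authors' values (0.084), range 0.000506 to 0.084. TPX2 failed without positive day 14 replicate 3 (0.0559) and negative day 14 replicate 1 (0.0635), range 2.78e-05 to 0.0635. NKX2-5 passed without negative day 14 replicates 2 (0.0406) and 3 (0.0479) and with normexp (0.0303), no correction (0.0229), authors' values (0.0438), replicate block (0.0202), daily block (0.00886), array weights (0.0158) and a reduced model (0.0159), range 0.00886 to 0.177. VCAM1 (0.0149, range 0.0149 to 0.427) passed with daily block. Among lists, pluripotency had adjusted p = 0.0529 with the replicate block and 0.12 with the daily block (range 0.000244 to 0.351), glycolysis had 0.0935 with authors' values and 0.264 with arrays 3 left out (range 0.0158 to 0.467), Wnt pathway had 0.189 with authors' values (range 0.0281 to 0.351) and BMP and TGF-beta pathway had 0.0696 with arrays 3 left out (range 0.0192 to 0.351).

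From day 5 to day 14 MYH6 (6.69 ± 0.46) went from 7.30 ± 0.89 to 13.99 ± 0.04 in the positive fraction, a rise of at least 103-fold (adjusted p = 5.04e-09), and MYH7, the beta myosin heavy chain, rose at least 241-fold. MYOM1 (7.43 ± 0.86), a protein of the sarcomere's M-band, HSPB7 (at least 94.2-fold), a small heat shock protein of heart muscle, and MB (at least 91.6-fold), which encodes myoglobin, rose as well. AFP (7.23 ± 0.71, dim), a product of yolk sac and fetal liver, and HBZ (at least 162-fold), the embryonic zeta globin, rose too. LIN28A (-4.15 ± 0.23) fell 17.8-fold, and POU5F1 (at least 5.55-fold) fell below detection.

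Sarcomere genes rose for 23 of 24 (24 list-alone), with MYH7 and MYOM1 (camera adjusted p = 2.27e-15, adjusted p = 0.12 with estimated correlation). Calcium handling and ion channel genes rose for 12 of 19 and fell for 1 (12 and 1 list-alone), with PLN (5.50 ± 0.69, dim), which encodes phospholamban, and HRC (5.50 ± 0.72) (camera adjusted p = 5.69e-07, adjusted p = 0.0932 with estimated correlation). Cardiac transcription factors rose for 9 of 20 and fell for 2 (9 and 3 list-alone), with SMYD1 (5.83 ± 0.75), a muscle methyltransferase, and NKX2-5 (4.81 ± 0.78, dim) (camera adjusted p = 0.00191, adjusted p = 0.234 with estimated correlation). Liver and yolk sac endoderm genes rose for 14 of 16 (14 list-alone), with AFP and TF (at least 24.9-fold), which encodes transferrin (camera adjusted p = 4.6e-08, adjusted p = 0.229 with estimated correlation). Neuroectoderm genes rose for 8 of 18 and fell for 2 (9 and 2 list-alone), with LHX2 (2.79 ± 0.51) and STMN2 (2.51 ± 0.56, dim) (camera adjusted p = 0.00377, adjusted p = 0.0932 with estimated correlation). Cell cycle genes fell for 26 of 27 (26 list-alone), with AURKB (-2.39 ± 0.16) and CCNA2 (-1.98 ± 0.22) (camera adjusted p = 1.83e-17, adjusted p = 0.0932 with estimated correlation). Pluripotency genes fell for 9 of 14 (9 list-alone), with LIN28A and DNMT3B (-3.01 ± 0.32) (camera adjusted p = 1.2e-05, adjusted p = 0.0932 with estimated correlation). Other lists that rose were atrial or ventricular genes, smooth muscle, blood, oxidative phosphorylation, fatty acid oxidation, Wnt pathway, BMP and TGF-beta pathway, hypoxia and stress and immediate early response (camera adjusted p from 0.000219 to 0.0463), with adjusted p from 0.12 to 0.392 with estimated correlation.

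SIRPA (3.56 ± 0.30) rose 11.8-fold (adjusted p = 3.23e-08), and the surface adhesion molecule VCAM1 at least 49.3-fold (adjusted p = 7.28e-07). MYL2 (at least 34.9-fold) and PAX6 (at least 3.47-fold) rose, while PDGFRA (-1.47 ± 0.43) and MKI67 (-1.38 ± 0.24, dim) fell (adjusted p = 0.011 and 0.000133). The largest falls besides LIN28A were in RNA28SN5 (-5.41 ± 1.16, dim), a ribosomal RNA, CALB2 (-4.51 ± 0.36), SNORD3D (-4.30 ± 0.47, dim), a small nucleolar RNA with near-identical copies, and the pepsinogens PGA5 (-4.41 ± 0.61) and PGA3 (-4.22 ± 0.57). SOX2 (1.45 ± 0.60, dim), PECAM1 (0.82 ± 0.40, dim), ISL1 (0.57 ± 0.42), MESP1 (-0.33 ± 0.34, dim) and KDR (-0.29 ± 0.42) did not pass (adjusted p from 0.0631 to 0.627).

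In the positive fraction 2219 genes rose and 2434 fell at limma's adjusted p under 0.05. Of these calls 47.7% were rises, against 36.7% with scaling and 34.1% with the authors' values. Scaling moved the median change of all genes from -0.03 to -0.11 log2 units, and loess moved it to 0.06. Falls numbered 3897 with authors' values. PECAM1 passed without day 14 replicate 1 (0.0449) and with authors' values (0.0278) and array weights (0.0365), range 0.0278 to 0.457. SOX2 passed without day 14 replicate 2 (0.0481) and with loess (0.0152), scaling (0.0424), replicate block (0.0159), array weights (0.0485) and a reduced model (0.0435), range 0.0152 to 0.287. PDGFRA failed without day 14 replicate 3 (0.0701), range 0.000104 to 0.0701. Among lists, oxidative phosphorylation had adjusted p = 0.686 with authors' values (range 0.000307 to 0.686), hypoxia had 0.076 with authors' values and 0.0944 with arrays 3 left out (range 0.0227 to 0.27) and blood had 0.0988 with arrays 3 left out (range 0.00666 to 0.392).

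In the negative fraction PAX6 rose at least 39-fold (adjusted p = 3.1e-11), RAX (at least 74.8-fold) rose likewise, and SIX6 (6.01 ± 0.20, dim), an eye field factor, rose 64.4-fold. HES5 (5.53 ± 0.38) rose as well. MYH6 (5.61 ± 0.46) went from 7.59 ± 0.16 to 13.20 ± 0.78, a rise of at least 48.8-fold (adjusted p = 1.65e-08), AFP (5.86 ± 0.71) rose 58.1-fold and HBZ (at least 85.7-fold) rose too. POU5F1 fell at least 60.4-fold to below detection (adjusted p = 2.78e-10).

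Neuroectoderm genes rose for 13 of 18 (13 list-alone), with PAX6 and HES5 (camera adjusted p = 8.86e-09, adjusted p = 0.000413 with estimated correlation). Liver and yolk sac endoderm genes rose for 14 of 16 (15 list-alone), with AFP and TF (at least 20.4-fold) (camera adjusted p = 1.59e-08, adjusted p = 0.409 with estimated correlation). Sarcomere genes rose for 12 of 24 (13 list-alone), with MYH6 and MYH7 (at least 34.5-fold) (camera adjusted p = 8.57e-06, adjusted p = 0.549 with estimated correlation). Pluripotency genes fell for 11 of 14 (11 list-alone), with POU5F1 and PRDM14 (at least 14.6-fold) (camera adjusted p = 1.11e-09, adjusted p = 0.0123 with estimated correlation). Cell cycle genes fell for 9 of 27 and rose for 1 (10 and 1 list-alone), with MCM5 (-1.36 ± 0.15) and BUB1 (-1.22 ± 0.24) (camera adjusted p = 0.0384, adjusted p = 0.769 with estimated correlation). Further lists that rose were calcium handling and ion channels, atrial or ventricular genes, Notch pathway and hypoxia (camera adjusted p from 0.00596 to 0.0475), with adjusted p from 0.0947 to 0.549 with estimated correlation. The surface ectoderm list was the only other one that fell (camera adjusted p = 0.00188, adjusted p = 0.436 with estimated correlation).

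The largest other falls were in RNA28SN5 (-6.27 ± 1.16, dim) and RNA5S9 (-4.56 ± 0.56), ribosomal RNAs, CFAP95 (-5.98 ± 0.29, dim), GRPR (-5.28 ± 0.41), a peptide receptor, and ZSCAN10 (-4.97 ± 0.37, dim), a zinc finger factor of stem cells. VCAM1 (at least 14.9-fold), MYL2 (at least 4.1-fold) and SIRPA (1.09 ± 0.30) rose (adjusted p = 5.25e-05, 0.00238 and 0.0081), and PDGFRA (-1.77 ± 0.43) and KDR (-1.45 ± 0.42, dim) fell (adjusted p = 0.00326 and 0.0102). NKX2-5 (at least 3.1-fold), SOX2 (1.14 ± 0.60), MESP1 (-0.30 ± 0.34, dim), MKI67 (-0.19 ± 0.24), ISL1 (-0.33 ± 0.42) and PECAM1 (0.22 ± 0.40, dim) did not pass (adjusted p from 0.0875 to 0.707).

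In the negative fraction 2127 genes rose and 2287 fell at limma's adjusted p under 0.05. In both fractions 928 genes rose (375 if independent) and 1074 fell (443), and 196 were called in opposite directions. Falls numbered 3947 with authors' values. KDR failed without day 5 replicate 1 (0.0753), range 0.00272 to 0.0753. NKX2-5 passed without day 14 replicate 1 (0.0147) and with loess (0.0274), scaling (0.0335), replicate block (0.0375) and array weights (0.0491), range 0.0147 to 0.279. SOX2 passed with no correction (0.0397) and a reduced model (0.0276), range 0.0276 to 0.404. SIRPA (0.116, range 0.00136 to 0.116) failed with authors' values. Among lists, hypoxia had adjusted p = 0.0504 with authors' values (range 0.0145 to 0.409) and calcium handling and ion channels had 0.0891 with arrays 3 left out (range 0.00292 to 0.549).

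**Figure D3:**
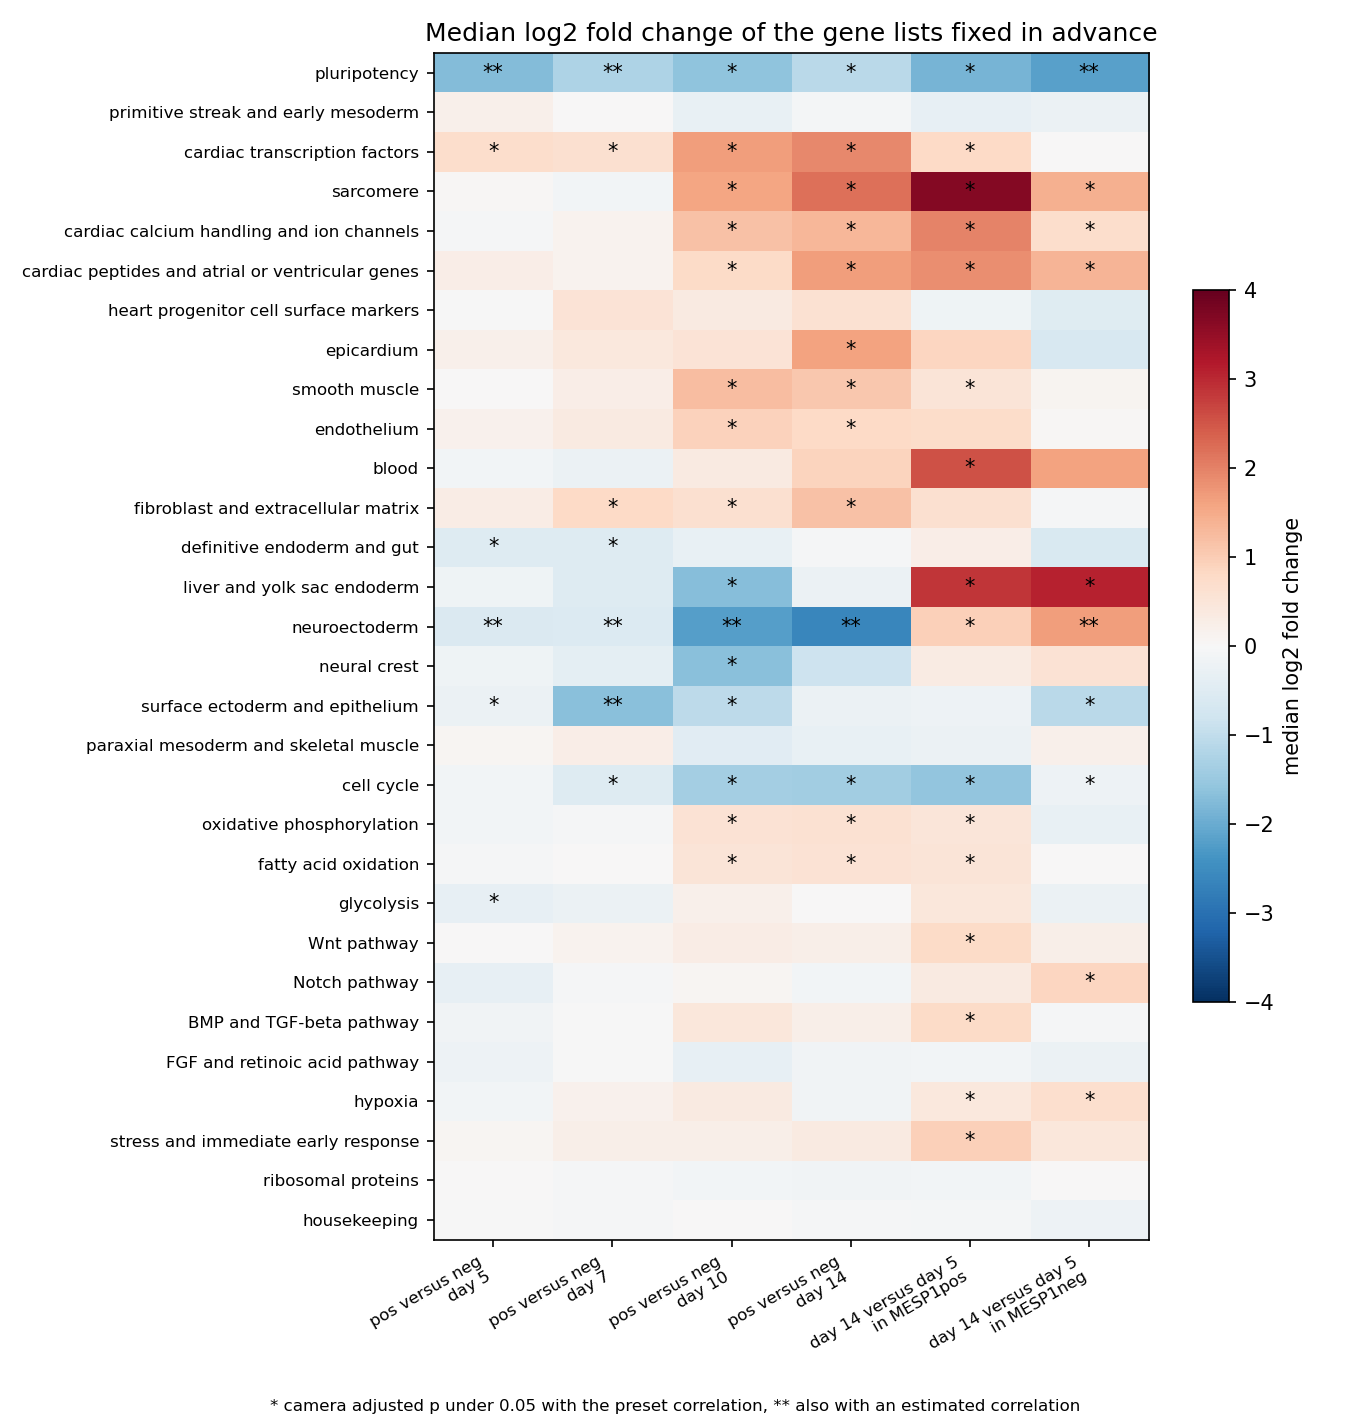
Median log2 fold change (colour) of each of the 30 gene lists (vertical axis) in 6 comparisons (horizontal axis), the 4 fraction comparisons and the day 14 versus day 5 change in each fraction. A single star marks a camera adjusted p under 0.05 with the preset correlation and a double star one that also passed with an estimated correlation, which the neuroectoderm list did in all 4 fraction comparisons.

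Between days 5 and 7 MYH6 (5.89 ± 0.46) went from 7.30 ± 0.89 to 13.19 ± 0.79, a rise of at least 59.5-fold (adjusted p = 1.63e-07), and SMYD1 (4.29 ± 0.75), SORBS2 (at least 16.1-fold), an adaptor protein of the Z-disc, and TECRL (3.95 ± 0.49) rose with it. NKX2-5 (2.87 ± 0.78, dim) rose, SIRPA (2.69 ± 0.30) rose 6.47-fold and VCAM1 at least 4.53-fold, and POU5F1 (-2.39 ± 0.39, dim) fell 5.24-fold. DCN (4.68 ± 1.29), which encodes the matrix protein decorin and moved with array 3 (mean difference -3.17, SD 2.68 on day 7), and CSHL1 (4.39 ± 0.67, dim), of the placental lactogen family with its close copies, were the other large rises.

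Sarcomere genes rose for 11 of 24 (15 list-alone), with MYH6 and TNNC1 (3.80 ± 0.81) (camera adjusted p = 8.5e-08, adjusted p = 0.478 with estimated correlation). Calcium handling and ion channel genes rose for 6 of 19 and fell for 1 (7 and 1 list-alone), with HRC (3.59 ± 0.72) and PLN (3.55 ± 0.69, dim) (camera adjusted p = 0.00148, adjusted p = 0.41 with estimated correlation). Cardiac transcription factors rose for 7 of 20 (7 list-alone), with SMYD1 and NKX2-5 (camera adjusted p = 0.0161, adjusted p = 0.478 with estimated correlation). Cell cycle genes fell for 19 of 27 (22 list-alone), with AURKB (-1.33 ± 0.16) and MCM4 (-1.25 ± 0.19) (camera adjusted p = 1.52e-14, adjusted p = 0.368 with estimated correlation). Pluripotency genes fell for 5 of 14 (5 list-alone), with POU5F1 and ZFP42 (-1.86 ± 0.44) (camera adjusted p = 0.000637, adjusted p = 0.368 with estimated correlation). Other lists that rose were Wnt pathway and BMP and TGF-beta pathway (camera adjusted p from 0.00319 to 0.0192), with adjusted p from 0.41 to 0.478 with estimated correlation. The largest falls were in RNA28SN5 (-4.19 ± 1.16), PTGDS (-3.25 ± 0.28, dim), HS3ST3A1 (-3.21 ± 0.46), a heparan sulfate enzyme, TIMP4 (at least 6.71-fold), a metalloproteinase inhibitor, COL9A2 (-2.98 ± 0.39) and CFD (-2.93 ± 0.28, dim), which encodes complement factor D. AFP (1.85 ± 0.71, dim), ISL1 (0.77 ± 0.42), MESP1 (-0.62 ± 0.34, dim), PECAM1 (0.53 ± 0.40, dim), MKI67 (-0.30 ± 0.24), KDR (-0.18 ± 0.42), SOX2 (-0.21 ± 0.60, dim) and PDGFRA (-0.03 ± 0.43) did not pass (adjusted p from 0.0804 to 0.975), and MYL2 and PAX6 were detected in neither group.

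Between days 5 and 7, 901 genes rose and 1163 fell. The counts were 500 and 677 without day 5 replicate 2, 578 and 766 without day 5 replicate 3, and 731 genes fell without day 7 replicate 3. Rises and falls numbered 1813 and 1967 with array weights and 506 and 657 with a reduced model, and falls alone 1895 with scaling and 2818 with authors' values. RNA28SN5 failed without day 5 replicate 1 (0.0817) and day 7 replicate 3 (0.0834), range 0.000122 to 0.0834. NKX2-5 failed without day 5 replicates 2 (0.0538) and 3 (0.053) and day 7 replicates 1 (0.0501) and 3 (0.0942) and with arrays 3 left out (0.0728), range 0.000693 to 0.0942. DCN failed without day 5 replicates 2 (0.0667) and 3 (0.0739) and day 7 replicates 1 (0.0529) and 2 (0.0902) and with a reduced model (0.0559), range 4.49e-05 to 0.0902. AFP passed without day 7 replicate 1 (0.0254) and with loess (0.0317), scaling (0.0386) and replicate block (0.024), range 0.024 to 0.435. ISL1 passed without day 7 replicate 2 (0.00284) and with array weights (0.00183), range 0.00183 to 0.629. VCAM1 failed without day 7 replicate 3 (0.0599) and with no correction (0.0804), range 0.000177 to 0.0804. Among lists, pluripotency had adjusted p = 0.14 with authors' values (range 0.000206 to 0.368).

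Between days 7 and 10 MYH7 (4.28 ± 0.86) went from 6.05 ± 0.91 to 10.33 ± 0.99, a 19.4-fold rise (adjusted p = 0.00604), HSPB3 (4.71 ± 0.69, dim), a small heat shock protein of muscle, rose 26.1-fold, and SPHKAP (at least 15.1-fold), a kinase anchoring protein, rose too. CKM (4.59 ± 1.06, dim), the muscle creatine kinase, MYL3 (4.16 ± 0.97), a ventricular myosin light chain, and NPPA (4.09 ± 0.94, dim), the atrial natriuretic peptide, rose as well. VCAM1 (2.84 ± 0.68) and AFP (2.89 ± 0.71) rose (adjusted p = 0.0178 and 0.0212) and MKI67 (-0.94 ± 0.24, dim) fell (adjusted p = 0.027).

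Sarcomere genes rose for 10 of 24 (15 list-alone), with MYH7 and MYL3 (camera adjusted p = 5.99e-14, adjusted p = 0.188 with estimated correlation). Cell cycle genes fell for 13 of 27 (20 list-alone), with AURKB (-1.22 ± 0.16) and CCNB2 (-1.20 ± 0.17) (camera adjusted p = 2.65e-19, adjusted p = 0.11 with estimated correlation). Further lists that rose were cardiac transcription factors, calcium handling and ion channels, atrial or ventricular genes, smooth muscle, endothelium, blood, liver and yolk sac endoderm, neuroectoderm, oxidative phosphorylation, fatty acid oxidation, glycolysis and Wnt pathway (camera adjusted p from 4.6e-08 to 0.0277), with adjusted p from 0.11 to 0.505 with estimated correlation. The pluripotency list was the only other one that fell (camera adjusted p = 0.00158, adjusted p = 0.188 with estimated correlation). The largest falls were in DNAH2 (-2.40 ± 0.45), a dynein chain of cilia, CALB2 (-2.16 ± 0.36), SORL1 (-2.05 ± 0.33), a sorting receptor, LCN15 (-1.93 ± 0.33), a lipocalin, and the small nucleolar RNAs SNORD3D (-1.92 ± 0.47) and SNORD3A (-1.78 ± 0.50). PAX6 (at least 1.33-fold), SIRPA (0.81 ± 0.30), NKX2-5 (1.85 ± 0.78), PDGFRA (-1.01 ± 0.43), MYL2 (at least 1.42-fold), SOX2 (0.92 ± 0.60, dim), POU5F1 (at least 1.03-fold), PECAM1 (0.60 ± 0.40), ISL1 (0.48 ± 0.42), KDR (0.22 ± 0.42) and MESP1 (-0.09 ± 0.34, dim) did not pass (adjusted p from 0.101 to 0.948).

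Between days 7 and 10, 355 genes rose and 202 fell. The counts were 163 and 80 without day 7 replicate 1, 200 and 89 without day 10 replicate 2, and 205 and 102 without day 10 replicate 3. Rises and falls numbered 602 and 391 with the replicate block, 801 and 641 with array weights, 39 and 4 with a reduced model and 144 and 38 with authors' values. CKM failed without day 7 replicates 1 (0.0935) and 2 (0.063) and day 10 replicate 3 (0.0724) and with a reduced model (0.0912), range 0.000255 to 0.0935. MYL3 failed without day 7 replicates 1 (0.0894) and 2 (0.0694) and day 10 replicates 2 (0.0596) and 3 (0.0625) and with a reduced model (0.0695), range 0.00129 to 0.0894. NPPA failed without day 7 replicates 1 (0.065) and 2 (0.0677) and day 10 replicate 3 (0.0783) and with a reduced model (0.0757), range 0.00246 to 0.0783. VCAM1 failed without day 7 replicates 1 (0.0555) and 2 (0.0902) and day 10 replicates 2 (0.0583) and 3 (0.0891) and with a reduced model (0.0772), range 0.000674 to 0.0902. AFP failed without day 7 replicates 1 (0.145) and 3 (0.0739) and day 10 replicates 2 (0.126) and 3 (0.0629) and with arrays 3 left out (0.131) and a reduced model (0.256), range 0.000197 to 0.256. MKI67 failed without day 7 replicates 1 (0.111) and 3 (0.0878) and day 10 replicates 2 (0.0889) and 3 (0.162) and with loess (0.056), scaling (0.0697), authors' values (0.148), no filter (0.0559), arrays 3 left out (0.138) and a reduced model (0.229), range 0.00248 to 0.229. SNORD3D failed without day 7 replicate 1 (0.135) and day 10 replicates 1 (0.0594) and 2 (0.103) and with no correction (0.0726), authors' values (0.155) and a reduced model (0.133), range 0.00103 to 0.155. SNORD3A failed without day 7 replicate 1 (0.258) and day 10 replicates 1 (0.0834), 2 (0.112) and 3 (0.103) and with normexp (0.0858), no correction (0.124), loess (0.0567), scaling (0.061), authors' values (0.254), no filter (0.0568), arrays 3 left out (0.082) and a reduced model (0.146), range 0.00417 to 0.258. SIRPA passed without day 7 replicate 3 (0.0463), range 0.0463 to 0.482. PDGFRA (0.0399, range 0.0399 to 0.676) and PECAM1 (0.0447, range 0.0447 to 0.939) passed with array weights. AURKB (0.0897, range 1.9e-05 to 0.0897), CCNB2 (0.069, range 3.62e-05 to 0.069), DNAH2 (0.0818, range 8.57e-05 to 0.0818), CALB2 (0.0698, range 0.000197 to 0.0698) and SORL1 (0.0695, range 2.23e-05 to 0.0695) failed with a reduced model. Among lists, atrial or ventricular genes had adjusted p = 0.0801 with authors' values and 0.151 with arrays 3 left out (range 0.0134 to 0.388), neuroectoderm had 0.178 with authors' values and 0.156 with arrays 3 left out (range 0.0151 to 0.178) and blood had 0.125 with arrays 3 left out (range 0.00523 to 0.388).

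Between days 10 and 14 few genes changed in limma's model of all arrays, and of those named here as changed only SIX6 was also called with a reduced model. MYL2 (4.62 ± 0.58, dim) went from 5.39 ± 1.19 to 10.01 ± 0.52, a 24.6-fold rise (adjusted p = 0.000223), and ITLN1 (5.47 ± 0.73, dim) rose 44.4-fold (adjusted p = 0.000387). TF (3.11 ± 0.44), SFRP2 (3.09 ± 0.36), a secreted Wnt modulator, CCL2 (3.07 ± 0.47, dim), a chemokine, SIX6 (3.05 ± 0.20, dim) and PAX6 (1.38 ± 0.30) rose too. The falls were led by the pepsinogens PGA5 (-3.56 ± 0.61), PGA3 (-3.34 ± 0.57) and PGA4 (at least 2.04-fold), GRP (at least 4.86-fold), a peptide hormone, VWF (-1.55 ± 0.27, dim), the von Willebrand factor, and LIN28A (-1.41 ± 0.23).

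Liver and yolk sac endoderm genes rose for 2 of 16 (10 list-alone), with TF and ALB (2.72 ± 0.42), which encodes albumin (camera adjusted p = 9.31e-17, adjusted p = 0.186 with estimated correlation). Neuroectoderm genes rose for 4 of 18 (4 list-alone), with HES5 (2.38 ± 0.38, dim) and TUBB3 (1.68 ± 0.36) (camera adjusted p = 0.00103, adjusted p = 0.0415 with estimated correlation). Epicardium genes rose for 2 of 14 (3 list-alone), with ITLN1 and UPK3B (at least 1.89-fold), a marker of mesothelium (camera adjusted p = 0.00204, adjusted p = 0.488 with estimated correlation). Of 24 sarcomere genes 1 rose, MYL2, and 1 list-alone (camera adjusted p = 0.00601, adjusted p = 0.863 with estimated correlation). Other lists that rose were calcium handling and ion channels, atrial or ventricular genes and stress and immediate early response (camera adjusted p from 0.00103 to 0.0298), with adjusted p from 0.29 to 0.566 with estimated correlation. Other lists that fell were pluripotency and endothelium (camera adjusted p from 0.00562 to 0.0162), with adjusted p from 0.361 to 0.851 with estimated correlation. AFP (2.49 ± 0.71), NKX2-5 (0.08 ± 0.78), ISL1 (-0.68 ± 0.42), SIRPA (0.06 ± 0.30), VCAM1 (0.60 ± 0.68), PDGFRA (-0.43 ± 0.43), KDR (-0.32 ± 0.42), SOX2 (0.74 ± 0.60, dim), PECAM1 (-0.31 ± 0.40), MKI67 (-0.14 ± 0.24, dim) and MESP1 (0.38 ± 0.34, dim) did not pass (adjusted p from 0.217 to 1), and POU5F1 was detected in neither group.

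Between days 10 and 14, 39 genes rose and 11 fell. The counts were 19 and 5 without day 10 replicate 1, 23 and 6 without day 10 replicate 2, 22 and 7 without day 14 replicate 2, and 7 fell without day 14 replicate 1. Rises and falls numbered 65 and 23 with the replicate block, 1 and 0 with a reduced model and 23 and 5 with authors' values, and rises alone 19 with scaling. The model of all arrays had 706 genes at an unadjusted p under 0.05. PAX6 failed without day 10 replicates 1 (0.0839), 2 (0.161) and 3 (0.135) and day 14 replicates 1 (0.16) and 3 (0.0646) and with normexp (0.16), no correction (0.269), loess (0.0589), scaling (0.0819), authors' values (0.314), no filter (0.0646), array weights (0.122), arrays 3 left out (0.197) and a reduced model (0.752), range 0.0024 to 0.752. VWF failed without day 10 replicates 1 (0.0592) and 2 (0.0535) and with normexp (0.069), no correction (0.15), authors' values (0.623) and a reduced model (0.235), range 0.000759 to 0.623. TUBB3 failed without day 10 replicates 1 (0.134), 2 (0.0516) and 3 (0.199) and day 14 replicates 1 (0.0933), 2 (0.197) and 3 (0.0775) and with no correction (0.0545), authors' values (0.106), arrays 3 left out (0.0956) and a reduced model (0.166), range 0.00613 to 0.199. UPK3B failed without day 10 replicates 1 (0.102), 2 (0.103) and 3 (0.138) and day 14 replicates 1 (0.0683) and 2 (0.277) and with scaling (0.147), authors' values (0.221) and a reduced model (0.484), range 0.00174 to 0.484. GRP failed without day 10 replicate 2 (0.121) and day 14 replicate 3 (0.0511) and with no correction (0.0545), loess (0.0506), scaling (0.0646), authors' values (0.185), arrays 3 left out (0.13) and a reduced model (0.166), range 0.000712 to 0.185. HES5 failed with no correction (0.0857), authors' values (0.151) and a reduced model (0.166), range 0.00146 to 0.166. PGA4 failed with scaling (0.139), authors' values (0.614), arrays 3 left out (0.059) and a reduced model (0.235), range 0.000245 to 0.614. AFP passed with authors' values (0.045) and replicate block (0.0432), range 0.0432 to 0.84. PGA5 failed with arrays 3 left out (0.063) and a reduced model (0.158), range 0.00168 to 0.158. PGA3 failed with arrays 3 left out (0.0936) and a reduced model (0.135), range 0.00131 to 0.135. MYL2 (0.135, range 6.59e-06 to 0.135), ITLN1 (0.237, range 2.11e-07 to 0.237), TF (0.166, range 0.000198 to 0.166), SFRP2 (0.166, range 2.11e-07 to 0.166), CCL2 (0.135, range 2.46e-05 to 0.135), LIN28A (0.397, range 0.000436 to 0.397) and ALB (0.158, range 0.000991 to 0.158) failed with a reduced model. Among lists, calcium handling and ion channels had adjusted p = 0.0636 with the replicate block and 0.0978 with arrays 3 left out (range 0.0135 to 0.566), pluripotency had 0.148 with authors' values and 0.0827 with arrays 3 left out (range 0.00101 to 0.361) and endothelium had 0.112 with authors' values (range 0.00231 to 0.851).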

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

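The split counts were planned, and the tests of the arrays numbered 3, of the sarcomere genes at day 7 and of the liver genes were chosen after the results were seen.

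An interaction test showed that the difference between the fractions was higher at day 14 than at day 5 for 1140 genes and lower for 1151, and the F-test over days called 1930. The log2 differences named by the rule were those of ITLN1 (5.67), ADGRG2 (5.57), NMRK2 (5.27), ADM (4.50), PLAAT3 (4.49) and SMPDL3B (4.48) upwards and of ATP6V1B1 (-5.64), FABP7 (-4.55), ZBTB16 (-4.51), GRM3 (-4.13), CCKBR (-4.06) and DIPK1C (-3.98) downwards. ITLN1 was not detected on day 5 in either fraction and DIPK1C not in 1 fraction, so their sizes and ranks rest on background signal. Among 100 ways of dealing the fraction labels within each day, only the real one gave as many genes in each of these tests. The real values were 2291 and 1930 and the highest others 2259 and 1171. High counts came only where some day kept its true labels. The 80 interaction draws with no such day called 0 genes and the 59 F-test draws at most 2. Redealing also removes a constant difference, so it cannot test for a change.

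For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real count and the highest other were 1535 and 4 (day 5), 1363 and 94 (day 7), 2774 and 0 (day 10), 3586 and 0 (day 14), 4653 and 0 (14 versus 5, positive), 4414 and 0 (14 versus 5, negative), 2064 and 3 (7 versus 5), 557 and 41 (10 versus 7) and 50 and 56 (14 versus 10). As many genes as in the real split came from 1 split, the real one, except for day 14 versus day 10, where 2 did. The split that called 56 set day 10 replicates 1 and 3 and day 14 replicate 3 against the rest, and among the splits that part all replicate numbers the highest other count there was 0.

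Probes without a gene name here lie outside the gene comparisons. Of 4727 detected ones, 234 were higher and 414 lower in the positive fraction at day 14.

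Arrays 3 stood apart in both fractions, upwards in sarcomere genes. A low array 1 may add to this in the negative fraction (NKX2-5 5.40, 7.67 and 7.83 on day 10). The median sarcomere difference was at least 0.63 on the 3 arrays between the others in brightness. These can lie near 1 replicate, so brightness stays open. Normalisation is argued against by a mean difference of at least 0.66 under 5 other ways of processing, against 0.95. A different culture or run may be the source. It cannot be told apart, since the matrix genes moved too (mean -1.12) and no label gives a batch.

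Sarcomere genes as a list did not differ on average between the fractions at day 7. Replicates 1 to 3 conflicted for NKX2-5 (7.83, 5.85 and 8.85 positive, 5.38, 7.49 and 8.10 negative). Saturation is argued against by the 12 sarcomere genes of middle brightness. Their median difference was -0.16 (quartiles -0.38 to 0.27) at day 7 and 2.57 at day 14. An exchange of the fractions is argued against by a median of -1.23 for the pluripotency genes. Positive cells carried over as the only source are argued against by 167 genes at least 2-fold higher in the positive fraction. Such a source would need almost wholly positive cells. Early heart muscle arising in both fractions, or carried cells favouring it, stays open and untested.

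The liver and yolk sac endoderm list rose in both fractions, without passing with an estimated correlation (adjusted p = 0.229 positive, 0.409 negative). Bulk carry-over of negative cells is argued against by the liver genes' level in the positive fraction. It was 82.6% of that in the negative (quartiles 71.1 to 105), against 9.33% (5.94 to 51) for neuroectoderm genes. Normalisation is argued against by a median rise of at least 1.45 under 5 other ways of processing, against 2.87. Endoderm cells already present on day 5 may be the source and cannot be told apart, since 4 definitive endoderm and gut genes were lower at day 14 and a few such cells may lie below detection. Endoderm forming in both fractions, or carried cells favouring it, stays open and untested.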

How the results depend on the processing

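The daily block and leaving out arrays 3 were chosen after the data were seen. Pairs of numbers are genes higher and lower, and counts within 1.5 times the reported ones are left out.

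With at least a 2-fold change required the counts were 217 and 485 (day 5), 167 and 412 (day 7), 555 and 625 (day 10), 799 and 722 (day 14), 1170 and 843 (14 versus 5, positive), 916 and 753 (14 versus 5, negative), 397 and 315 (7 versus 5), 235 and 66 (10 versus 7) and 738 lower (the difference of changes). At adjusted p under 0.01 they were 272 and 542 (day 5), 184 and 490 (day 7), 677 and 898 (day 10), 1070 and 1173 (day 14), 1615 lower (14 versus 5, positive), 1370 and 1465 (14 versus 5, negative), 424 and 559 (7 versus 5), 146 and 68 (10 versus 7), 20 and 5 (14 versus 10), 547 and 614 (the difference of changes) and 1020 in the F-test. These settings tighten the threshold, which lowers the counts by construction.

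The replicate block gave 800 higher (day 7), 602 and 391 (10 versus 7) and 65 and 23 (14 versus 10). With the daily block the counts were 1261 higher (day 5), 1194 and 1378 (day 7), 2212 higher (day 10), 1988 and 1936 (the difference of changes) and 3660 in the F-test. Array weights gave 1409 and 1436 (day 5), 1282 and 1484 (day 7), 1813 and 1967 (7 versus 5), 801 and 641 (10 versus 7), 1763 and 1758 (the difference of changes) and 3618 in the F-test. A reduced model gave 1036 higher (day 5), 158 and 390 (day 7) and 802 and 907 (day 10). It gave 506 and 657 (7 versus 5), 39 and 4 (10 versus 7) and 1 and 0 (14 versus 10). Fewer arrays estimate its spread. Scaling gave 1895 lower (7 versus 5) and 19 higher (14 versus 10). The authors' values gave 224 and 533 (day 7), 820 and 954 (day 10), 1156 higher (day 14), 3897 lower (14 versus 5, positive), 3947 lower (14 versus 5, negative), 2818 lower (7 versus 5), 144 and 38 (10 versus 7) and 23 and 5 (14 versus 10). Except for the tighter thresholds, the cause of these moves was not tested. Leaving out 1 array at a time gave ranges of 326 to 523 and 607 to 732 (day 5), 234 to 583 and 530 to 887 (day 7), 778 to 1290 and 1004 to 1425 (day 10), 1256 to 1759 and 1319 to 1643 (day 14), 1815 to 2056 and 1988 to 2273 (14 versus 5, positive), 1602 to 1861 and 1722 to 2042 (14 versus 5, negative), 500 to 885 and 677 to 1054 (7 versus 5), 163 to 402 and 80 to 297 (10 versus 7), 19 to 53 and 5 to 15 (14 versus 10) and 806 to 1136 and 850 to 1116 (the difference of changes) and 1518 to 2135 in the F-test.

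Other background corrections, cyclic loess, other detection filters and testing every detected probe left each count within 1.5 times, as did leaving out the 6 arrays numbered 3. The probe intensities name no slide, so a slide block was not run. Of 5864 alternative results for 324 named gene results, 5573 had the same direction and side of the threshold, 220 lost a call, 71 gained 1 and 0 reversed direction past the threshold. Of 111 list calls, 11 passed with an estimated correlation, 109 with the replicate block, 99 with the authors' values and 100 without the 6 arrays numbered 3.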

Other observations

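Over all 6 groups of days 7, 10 and 14, 19 genes stood more than 1 log2 unit above and 40 more than 1 below the other replicates on every array numbered 3, against 10 and 4 for the arrays numbered 1 and 1 and 2 for those numbered 2.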
